A study of Homo sapiens with 58 samples.

How the data were processed

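Gene expression was measured in 58 rhabdomyosarcoma tumours, a childhood cancer with features of skeletal muscle, with 1 Affymetrix 3' expression array per tumour. The labels assign each tumour to 1 of 3 groups by its fusion gene, which joins the DNA-binding part of PAX3 or PAX7 to the activating part of FOXO1. There were 26 PAX3-FOXO1, 7 PAX7-FOXO1 and 25 fusion-negative tumours, so that 33 tumours were fusion-positive. The labels pair no samples and do not state whether each array came from a separate patient, so the p-values measure differences against the spread between arrays.

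The values deposited by the authors were log2 RMA values, background-corrected, quantile-normalized and summarized per probe set. The processing notes name the oligo package and RMA, whose versions are not given in the sources used here. The table held 54675 probe sets, and its values ran from 2.42 to 14.9, with array medians between 5.35 and 5.49. For arrays, their number limits the precision of each group mean.

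Gene symbols came from the probe annotation and were matched by gene ID to the GRCh38.p14 gene table, which was used only for names, chromosomes and neighbouring genes. Of the 41097 probe sets with a single symbol, 41037 had a gene ID in that table, 54 kept the symbol of the annotation and the rest were control probe sets. The 1801 probe sets with several symbols and the 11777 that the annotation did not list were not used in the comparisons. XIST, TSIX and genes of the Y chromosome, 59 probe sets in all, were left out before testing, as were the 62 control probe sets. Each of the 19740 genes was represented by its single-symbol probe set with the highest mean over the 58 arrays, and 10511 genes had more than 1 probe set. No filter was set on dim probe sets.

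Differences were tested with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with default settings, and p-values were adjusted by the Benjamini-Hochberg method over all genes. A gene passed at an adjusted p under 0.05, and a second count required at least a 2-fold difference. Fusion-positive and fusion-negative tumours were compared in a fit with 2 groups, and PAX3-FOXO1, PAX7-FOXO1 and fusion-negative tumours in a fit with 3 groups that shared their estimate of the spread. All tests were two-sided. Tables were read and plots drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

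The 29 gene lists covered the fusion partners, reported PAX-FOXO1 targets and fusion-positive markers, RAS-MAPK output, myogenic regulators, sarcomere and muscle differentiation, receptor tyrosine kinases with IGF2, neuronal genes and cell cycle. They also covered genes near CDK4 at 12q13-q14, near MYCN at 2p24 and at 13q31, imprinted genes at 11p15, HOX genes, the Hedgehog and Notch pathways, p53 targets, DNA methylation and Polycomb enzymes, and antigen presentation by MHC class I and class II. Markers of other cell types were those of fibroblasts and stroma, endothelial cells, smooth muscle and pericytes, T cells, macrophages, B and plasma cells, adult skeletal muscle, adipocytes and erythroid cells, beside a list of control genes. The list of reported targets came from general knowledge of other rhabdomyosarcoma work, which may include the study behind these arrays, so its direction is not independent evidence. Lists with at least 3 measured members were tested with camera, with the correlation between genes estimated per list and p-values adjusted over the 29 lists. A preset correlation of 0.01 and fry, which tests whether a list's genes move on balance 1 way without comparing them with other genes, were alternatives. Members past the threshold were counted over all genes and adjusted over the list alone.

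Genes were named by rule. These were the 10 largest differences in each direction among genes past the threshold for fusion status, the 5 in each direction between the fusions and the 3 in each direction for each fusion against fusion-negative tumours. Up to 2 members in each direction were named per list, with the most abundant marker of each other cell type and every probe set of PAX3, PAX7 and FOXO1. Symbols naming only a clone or open reading frame were passed over. The groups, comparisons, gene lists, naming rule and 91 pairs of result and alternative were chosen before the data were examined.

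RNA quality was measured per array as the mean 3' minus 5' log2 value of the GAPDH and ACTB control probe sets. Group means were compared by permutation with 100000 resamples, or by an exact permutation test where a group held fewer than 10 tumours. Titles follow 2 styles, here called the numbered series of 42 tumours and the coded series of 16, which were treated as a possible batch. Correlations between sets of differences were computed across genes, which are not independent replicates, and the correlation between the 2 fusions was compared with 100 simulated draws.

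The limma step was tested on simulated data with 50 changed genes at each of 4 log2 sizes among 19740 genes. For fusion-positive versus fusion-negative it recovered 72% of changes of 0.5, 94% of changes of 1 and 100% of changes of 2 or 3, and 8 of the 191 genes called were unchanged. For PAX3-FOXO1 versus PAX7-FOXO1 it recovered 50%, 76%, 86% and 98% of changes of 0.5, 1, 2 and 3, and 5 of 160 called genes were unchanged. In each of these comparisons 1 list was shifted by a log2 difference of 1, and it was the list called. The simulated genes varied independently, whereas members of real lists were correlated, for example at an estimated 0.591 for the sarcomere list between the fusions. The simulation therefore does not show how readily the list test calls a shift in these tumours, and a list not called is not shown to be unchanged. Simulated values were also normally distributed, with the same spread in every group. The recovered shares and the unchanged genes called need not hold for genes that are uneven within a group. Alternatives covered the choice of probe set, a filter on dim genes, normalization between arrays, the variance model, array weights, covariates, rank-sum tests, parts of the samples and set tests. Each PAX7-FOXO1 tumour was also left out in turn.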

Results

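Expression was measured on 58 arrays of rhabdomyosarcoma, 26 of PAX3-FOXO1 tumours, 7 of PAX7-FOXO1 tumours and 25 of fusion-negative tumours. The values were log2 RMA values, and a difference of 1 is a 2-fold difference in signal. For 54 of the 58 tumours the most similar tumour had the same fusion status, 32 of the 33 fusion-positive and 22 of the 25 fusion-negative tumours. The first principal component held 14.7% of the variance, and fusion status accounted for 84.2% of that component and title series for 0.07%. The 3' minus 5' value, a sign of RNA degradation, was 1.98 ± 0.62 (SD, n = 33) in fusion-positive and 1.96 ± 0.88 (SD, n = 25) in fusion-negative tumours (difference 0.02, permutation p = 0.928). Within the title series the difference was -0.10 in the numbered (permutation p = 0.658) and 0.34 in the coded series (exact permutation p = 0.395). The numbered series held 24 fusion-positive and 18 fusion-negative tumours and the coded series 9 and 7 (Fisher's exact p = 1).

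**Figure D1:**
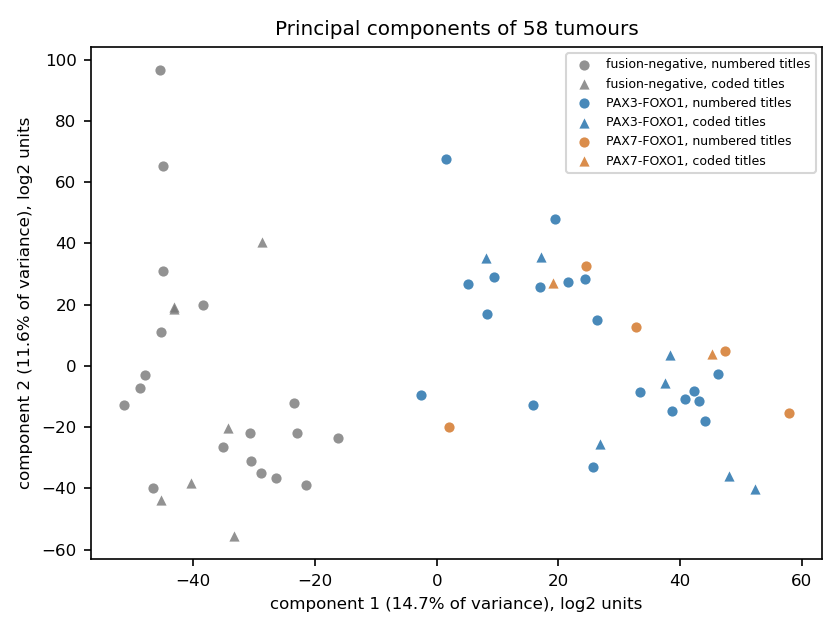
Each point is a tumour, placed by its first and second principal components over 19740 genes in log2 units, with colour for the fusion group and shape for the title series. Component 1 holds 14.7% of the variance, and fusion status accounts for 84.2% of it.

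The fused genes themselves were examined first, since their probe sets bear on the labels. PAX3, a transcription factor of embryonic muscle precursors, was higher in PAX3-FOXO1 than in fusion-negative tumours at 2 of its 4 probe sets. At the first it read 6.28 ± 0.58 (SD, n = 26) against 4.97 ± 0.59 (SD, n = 25), a log2 difference of 1.31 (adjusted p = 3.5e-09), and 4.92 ± 0.19 (SD, n = 7) in PAX7-FOXO1 tumours. The second gave a PAX3-FOXO1 minus fusion-negative difference of 1.12 (adjusted p = 2.5e-07). At both, the fusion-negative mean (4.97 and 4.53) lay under the median of every array, where signal is close to background, so these sizes are not exact. The other PAX3 probe sets, the one with the highest mean among them, differed by 0.28 (adjusted p = 0.728) and -0.08 (adjusted p = 0.691). PAX7, a transcription factor of muscle satellite cells, was lower in fusion-positive tumours at both of its probe sets, by log2 differences of -3.10 (adjusted p = 1.96e-05) and -1.06 (adjusted p = 1.25e-07). At either, 0 of 33 fusion-positive tumours lay above the fusion-negative median. The fusion-positive mean at the second PAX7 probe set (5.09) also lay under the median of every array. In PAX7-FOXO1 tumours alone the PAX7 differences from fusion-negative tumours were -1.50 (adjusted p = 0.311) and -0.74 (adjusted p = 0.0304). FOXO1, a forkhead transcription factor, was higher in PAX7-FOXO1 than in fusion-negative tumours by 1.11 (adjusted p = 0.0023) and 1.32 (adjusted p = 4.57e-04) at 2 of its 3 probe sets. In PAX3-FOXO1 tumours these FOXO1 probe sets differed by 0.05 (adjusted p = 0.882) and 0.13 (adjusted p = 0.667), and the dim remaining probe set passed in neither group. No probe positions were used, so these values do not separate a fusion transcript from the unfused gene.

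The comparison of fusion-positive with fusion-negative tumours, which the series was designed for, gave large differences in single genes. TFAP2B, an AP-2 family transcription factor, was higher in fusion-positive tumours, with 11.49 ± 1.07 (SD, n = 33) against 4.68 ± 1.65 (SD, n = 25). Its log2 difference was 6.81 ± 0.35 (SE, adjusted p = 1.27e-22). CNR1, a cannabinoid receptor, was higher by 5.94, at 10.85 ± 1.34 against 4.92 ± 2.07 (adjusted p = 2.94e-16). NOS1, the neuronal nitric oxide synthase, was higher by 5.79, at 10.32 ± 1.16 against 4.53 ± 1.26 (adjusted p = 5.02e-22). All 33 fusion-positive tumours lay above the fusion-negative median for these 3 genes. GAS2, a cytoskeleton-associated protein, was lower, at 4.09 ± 0.84 against 8.05 ± 2.37. Its log2 difference was -3.96 ± 0.44 (SE, adjusted p = 3.22e-10), and 0 of 33 fusion-positive tumours exceeded the fusion-negative median. For each of these 4 genes the lower group's mean lay under the median of every array, where signal is close to background, so the sizes of these differences are not exact ratios of transcript.

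Among the other genes with the largest measured increases were OLIG1, a transcription factor of the oligodendrocyte lineage (log2 difference 5.66, adjusted p = 4.84e-21), and PIPOX, a peroxisomal oxidase (5.34, adjusted p = 4.15e-22). They were followed by GREM1, a secreted BMP antagonist (4.82, adjusted p = 1.45e-10), and OTX2, a homeobox transcription factor of the forebrain (4.37, adjusted p = 9.56e-08). PITPNM3, BMP5, a secreted growth factor, and SORCS1, a sorting receptor, rose by 4.37, 4.36 and 4.35 (adjusted p = 1.78e-19, 1.87e-16 and 4.47e-16). For PITPNM3 every one of the 33 fusion-positive tumours exceeded every fusion-negative tumour. OTX2 was above the fusion-negative median in 30 of 33 tumours, GREM1 in 32 and the others in 33. Among the largest decreases were the cell adhesion gene CLMP (-3.61, adjusted p = 1.57e-12) and the neuronal pentraxin NPTX2 (-3.51, adjusted p = 3.4e-06). The microfibril gene FBN2 (-3.18, adjusted p = 5.91e-07) and the neurofilament gene NEFM (-3.14, adjusted p = 2.13e-05) fell as well. NNAT, an imprinted gene, fell with a difference of -3.08 (adjusted p = 1.76e-05) and the long non-coding RNA HOTAIR of the HOXC cluster with -3.01 (adjusted p = 6.43e-06). ZFHX4, a zinc-finger homeobox gene, fell with -2.88 (adjusted p = 2.71e-09) and the neurofilament gene NEFL with -2.82 (adjusted p = 1.26e-04). Of the 33 fusion-positive tumours, 0 exceeded the fusion-negative median for CLMP, HOTAIR and ZFHX4, 1 for NPTX2, FBN2 and NEFM, and 3 for NNAT and NEFL. Signal close to background also limited OLIG1, GREM1, OTX2, BMP5, SORCS1, CLMP, HOTAIR, NEFM and NEFL, whose lower group mean lay under the median of every array, so the order of these genes by size is not exact. In all this held for 17 of the 66 named genes past the threshold for fusion status, the remaining ones being OLIG2, MYF5, PPARG and AHSP.

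**Figure D2:**
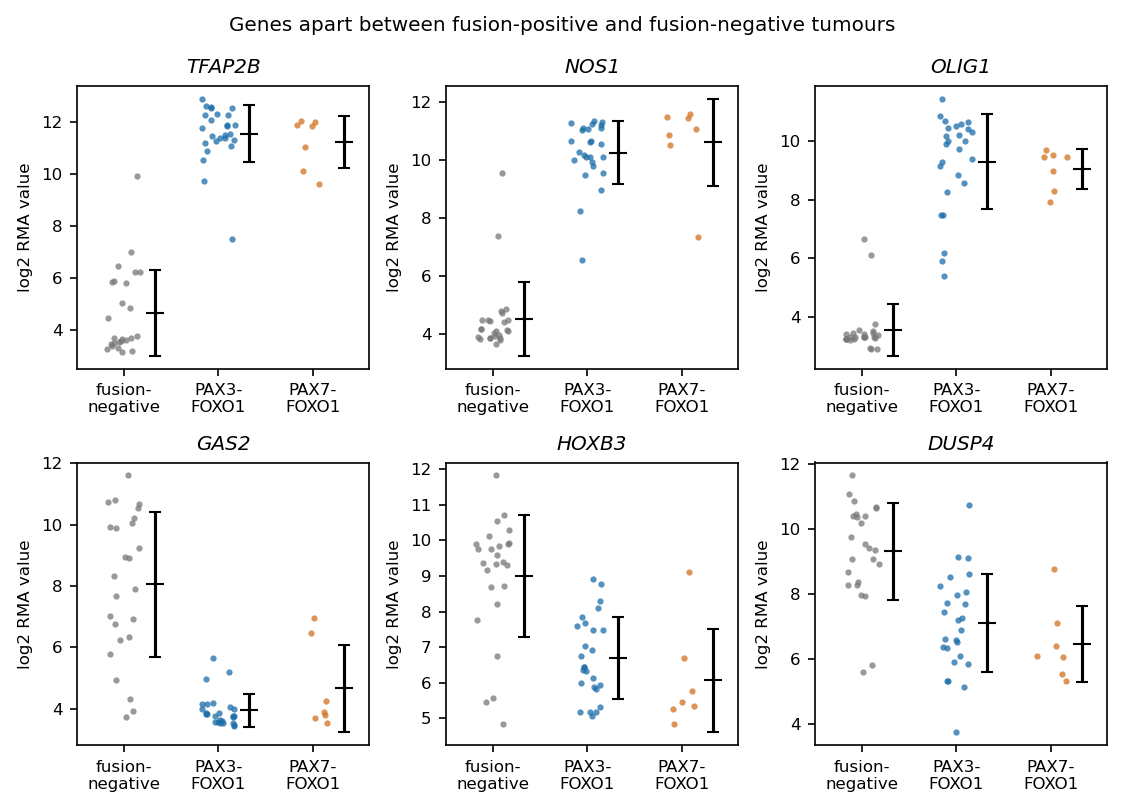
Each point is the log2 RMA value of 1 tumour for the gene named above its panel, and black marks give the group mean with its SD. TFAP2B, NOS1 and OLIG1 lie higher in both fusion groups than in fusion-negative tumours and GAS2, HOXB3 and DUSP4 lower, with TFAP2B means of 11.49 in fusion-positive and 4.68 in fusion-negative tumours.

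Of 26 reported PAX-FOXO1 targets and fusion-positive markers, 25 rose and 0 fell, and 25 rose adjusted over the list alone (camera adjusted p = 1.85e-10 with an estimated correlation). That list comes from general knowledge of other rhabdomyosarcoma work, which may overlap with these tumours, and is not independent evidence of its direction. Its members also appear in other lists, whose counts of higher genes are therefore not separate from it. These are ALK, FGFR2, FGFR4, MET and IGF1R among the kinases and DCX, NHLH1 and OLIG2 among the neuronal genes. MYCN at 2p24, MYOD1 among the myogenic regulators and JARID2 among the Polycomb enzymes are shared as well. Receptor tyrosine kinases with IGF2 moved both ways, with 8 of 20 higher and 3 lower (8 and 6 adjusted over the list alone; adjusted p = 0.512 with an estimated correlation). ALK rose with a log2 difference of 3.49 (adjusted p = 4.1e-14) and FGFR2 with 3.39 (adjusted p = 2.37e-09), in 33 and 32 of 33 tumours. EGFR fell (-2.26, adjusted p = 3.22e-07, 32 of 33 tumours below the fusion-negative median), though 2 of its 9 probe sets passed in the other direction. EPHA3, an ephrin receptor, fell too (-1.90, adjusted p = 0.00562, 32 of 33). Neuronal genes included 8 of 20 higher and 2 lower (9 and 4 adjusted over the list alone; adjusted p = 0.296 with an estimated correlation). OLIG1 and OLIG2, a related transcription factor (4.22, adjusted p = 7.72e-19, 33 of 33), were highest and NEFM and NEFL lowest. Of 5 genes near MYCN at 2p24, 3 rose, and 3 adjusted over the list alone (adjusted p = 0.452 with an estimated correlation). They included MYCN, a MYC family oncogene (1.80, adjusted p = 6.41e-07, 33 of 33), and CYRIA (0.47, adjusted p = 0.0178, 27 of 33). For MYCN the difference was 0.05 (adjusted p = 0.255) as the median of its 10 probe sets and 0.08 (adjusted p = 0.359) without the _x_at and _s_at probe sets.

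Muscle genes moved in both directions. Among 10 measured myogenic regulators 3 rose and 3 fell (4 and 3 adjusted over the list alone; adjusted p = 0.951 with an estimated correlation). MYOG, which drives terminal muscle differentiation, rose by 1.46 (adjusted p = 8.12e-06, 33 of 33 tumours) and EYA2, a transcriptional co-activator, by 2.10 (adjusted p = 1.45e-05, 31 of 33). MYF5, an early myogenic factor, and MYF6 fell with differences of -2.39 (adjusted p = 0.0035, 29 of 33 tumours below the fusion-negative median) and -1.28 (adjusted p = 0.0298, 26 of 33). MYF5 differed from fusion-negative tumours by -2.81 with PAX3-FOXO1 (adjusted p = 0.00101) and by -0.85 with PAX7-FOXO1 (adjusted p = 0.676), and between the fusions by -1.95 (adjusted p = 0.49). MYF6 differed by -1.67 with PAX3-FOXO1 (adjusted p = 0.00431) and by 0.18 with PAX7-FOXO1 (adjusted p = 0.917), and between the fusions by -1.85 (adjusted p = 0.237). Its call was lost with equal weight of the 2 fusions (-0.75, adjusted p = 0.285), with a rank-sum test (adjusted p = 0.0799) and in the numbered (-1.27, adjusted p = 0.103) and coded series alone (-1.31, adjusted p = 0.458). Of 29 sarcomere and muscle differentiation genes 4 rose and 0 fell (4 and 0 adjusted over the list alone; adjusted p = 0.951 with an estimated correlation). They included the giant sarcomere protein TTN (2.39, adjusted p = 4.71e-04, 33 of 33), for which 2 of 6 probe sets passed in the other direction, and MYOZ2 (1.87, adjusted p = 0.0226, 26 of 33), whose call was lost without the 5 arrays of highest 3' minus 5' value (adjusted p = 0.0956) and without the 3 least correlated arrays (adjusted p = 0.0546). With PAX3-FOXO1 alone 3 genes were higher and 2 lower than in fusion-negative tumours, the same adjusted over the list alone (median -0.11, adjusted p = 0.989 with an estimated correlation). With PAX7-FOXO1 alone 8 were higher and 0 lower, or 10 and 0 adjusted over the list alone (median 1.64, adjusted p = 0.424 with an estimated correlation, 1.84e-09 with the preset correlation). Adult skeletal muscle markers moved with them, as 6 of 15 were higher and 0 lower with PAX7-FOXO1 alone, or 9 and 0 adjusted over the list alone (median 1.54, adjusted p = 0.416 with an estimated correlation, 7.28e-06 with the preset correlation). CKM, MYH2 and MYH7 belong to both lists, so a part of this likeness is given by the lists themselves.

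Most measured HOX genes, which set position along the body axis, were lower in fusion-positive tumours. Of 28 measured members 18 fell and 0 rose, and 19 fell adjusted over the list alone (camera adjusted p = 0.0527 with an estimated correlation, 9.65e-09 with the preset correlation). HOXB3 fell with a difference of -2.42 (adjusted p = 1.78e-06) and HOXD4 with -2.22 (adjusted p = 8.31e-08), and 0 of 33 fusion-positive tumours exceeded the fusion-negative median for either. Beside the preset correlation and fry, the list passed under 4 alternatives, with adjusted p = 0.047 with title series as a covariate, 0.0362 among genes above the median mean, 0.0333 after quantile normalization and 0.0478 with the median of each gene's probe sets. It missed the threshold with the 3' minus 5' covariate (adjusted p = 0.0516) and with camera on ranks (adjusted p = 0.21). RAS-MAPK output genes, transcribed upon signalling through that cascade, fell in 11 of 17 cases and rose in 0 (12 and 0 adjusted over the list alone; adjusted p = 0.296 with an estimated correlation). DUSP4, a MAP kinase phosphatase, fell with -2.35 (adjusted p = 4.34e-06, 32 of 33) and CCND1, cyclin D1, with -1.45 (adjusted p = 0.005, 28 of 33). Hedgehog pathway genes fell in 6 of 11 cases and rose in 0 (7 and 0 adjusted over the list alone; adjusted p = 0.371 with an estimated correlation). GLI3, a transcription factor of the pathway, fell with -1.02 (adjusted p = 9.11e-05) and the receptor PTCH1 with -0.90 (adjusted p = 0.00325), below the fusion-negative median in 31 and 29 of 33 tumours. With PAX3-FOXO1 alone 4 Hedgehog genes were lower and 0 higher, or 7 and 0 adjusted over the list alone (median -0.575). With PAX7-FOXO1 alone 0 passed, or 2 lower and 1 higher adjusted over the list alone (median -0.484). Between the fusions 0 of the 11 passed.

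Other lists had mixed or few changes, all with adjusted p = 0.951 with an estimated correlation. Notch pathway genes rose in 2 and fell in 4 of 15 cases, the same numbers adjusted over the list alone. The ligand DLL1 (1.26, adjusted p = 6.07e-06) and NOTCH1 (0.50, adjusted p = 0.0218) were higher and the target genes HEY1 (-1.50, adjusted p = 2.94e-04) and HES1 (-1.36, adjusted p = 5.08e-05) lower. HES1 was 0.0621 (adjusted p = 0.395) without the _x_at and _s_at probe sets. The NOTCH1 call was lost with equal weight of the 2 fusions (0.36, adjusted p = 0.162) and without the 3 least correlated arrays (0.35, adjusted p = 0.0656). Of 13 p53 targets 1 rose and 3 fell, also adjusted over the list alone. SESN1 (0.63, adjusted p = 0.00623) rose, and the death receptors FAS (-1.15, adjusted p = 8.6e-04) and TNFRSF10B (-0.56, adjusted p = 0.0291) were among those that fell. Of 14 DNA methylation and Polycomb enzymes 2 rose and 2 fell (3 and 2 adjusted over the list alone). These were JARID2 (0.64, adjusted p = 3.81e-05) and SUZ12 (0.32, adjusted p = 0.0117) against EED (-0.56, adjusted p = 1.25e-04) and the methyltransferase DNMT1 (-0.53, adjusted p = 0.0223). Of 26 cell cycle genes 1 rose and 0 fell, also adjusted over the list alone. It was SKP2, part of an E3 ubiquitin ligase (1.10, adjusted p = 5.77e-04). Of 6 imprinted genes at 11p15 only TSSC4 fell (-0.42, adjusted p = 2.99e-04) and 0 rose, also adjusted over the list alone. With PAX3-FOXO1 alone 1 of the 6 was higher and 2 lower than in fusion-negative tumours, also adjusted over the list alone. With PAX7-FOXO1 alone 1 was higher and 1 lower, or 2 and 1 adjusted over the list alone. The list then had adjusted p = 0.989 and 0.699 with an estimated correlation. Of 13 genes of MHC class I presentation 1 rose, the peptide transporter TAP2 (0.82, adjusted p = 0.0201), and 1 adjusted over the list alone. With limma, 0 of 12 genes near CDK4 (1 at an unadjusted p under 0.05), 0 of 3 at 13q31 (0) and 0 of 10 of MHC class II (0) passed, and 0 of each adjusted over the list alone. Of the 3 fusion partners 1 fell, PAX7, and 1 of the 10 control genes rose, HPRT1 (0.41, adjusted p = 0.0296), or 0 adjusted over the list alone. Calls were lost without the _x_at and _s_at probe sets for EPHA3 (-0.01, adjusted p = 0.811), JARID2 (0.04, adjusted p = 0.655), FAS (-0.20, adjusted p = 0.195) and EED (-0.13, adjusted p = 0.727). As the median of their probe sets PTCH1 (-0.19, adjusted p = 0.187), SUZ12 (0.09, adjusted p = 0.783), TAP2 (0.28, adjusted p = 0.0863), EED (-0.35, adjusted p = 0.102), SKP2 (0.86, adjusted p = 0.0766), TNFRSF10B (-0.37, adjusted p = 0.0572) and HPRT1 (0.20, adjusted p = 0.0603) lost theirs. With equal weight of the 2 fusions CYRIA (0.43, adjusted p = 0.0598), SUZ12 (0.23, adjusted p = 0.115), TAP2 (0.66, adjusted p = 0.108) and HPRT1 (0.37, adjusted p = 0.0975) lost their calls. So did HPRT1 without the 5 arrays of highest 3' minus 5' value (0.34, adjusted p = 0.0997) and CYRIA as the median of its probe sets (0.50, adjusted p = 0.102).

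**Figure D3:**
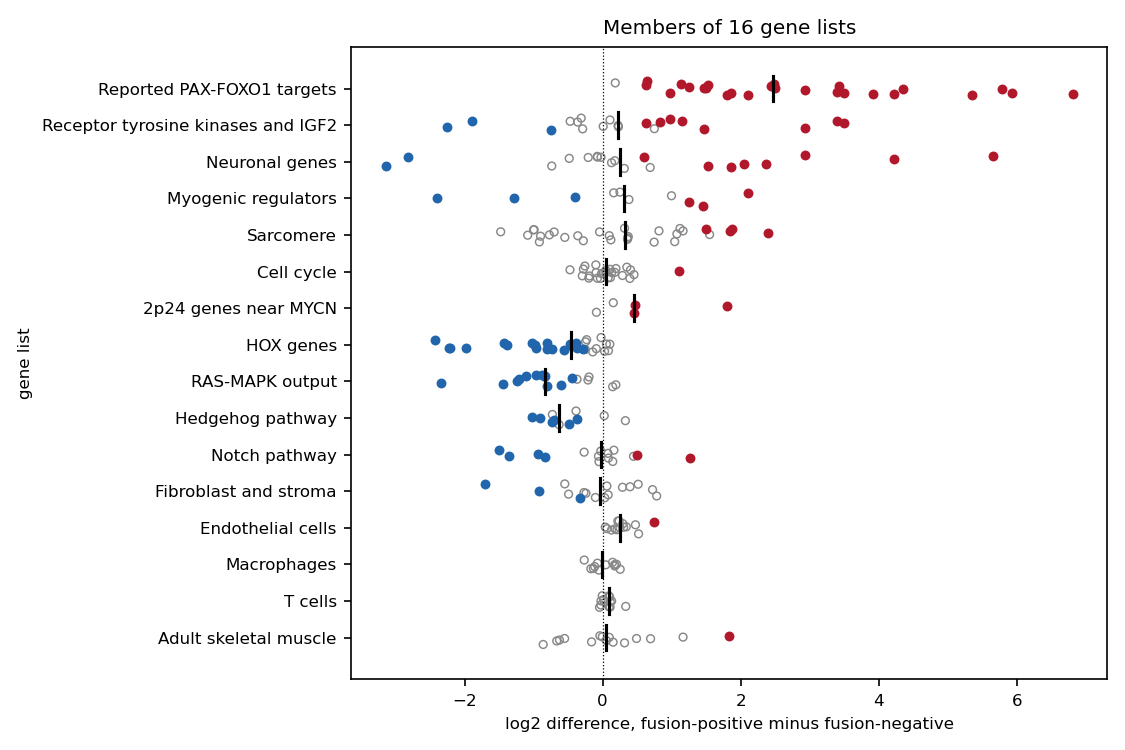
Each point is 1 member of a gene list, placed by its log2 difference between fusion-positive and fusion-negative tumours, filled red or blue when higher or lower at an adjusted p under 0.05 and open otherwise, and black bars mark list medians. Of the reported PAX-FOXO1 targets 25 of 26 are higher, and of the HOX genes 18 of 28 are lower.

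Between fusion-positive and fusion-negative tumours few markers of other cell types passed, and each list had adjusted p = 0.951 with an estimated correlation. Of 16 fibroblast and stroma genes 3 fell and 0 rose (3 lower and 3 higher adjusted over the list alone). These were the matrix protease MMP2 (-1.70, adjusted p = 3.54e-05, 28 of 33 tumours below the fusion-negative median), FBLN1 (-0.92, adjusted p = 0.019, 26 of 33) and the collagen COL3A1, the most abundant (-0.32, adjusted p = 0.0279, 22 of 33). MMP2 read 0.0227 (adjusted p = 0.797) and COL3A1 -0.32 (adjusted p = 0.0751) as the median of their probe sets. Of 12 smooth muscle and pericyte genes 1 rose and 3 fell, with the same numbers adjusted over the list alone. TAGLN rose (1.03, adjusted p = 0.0201, or 0.29 with adjusted p = 0.281 without the _x_at and _s_at probe sets), and NOTCH3 (-0.83, adjusted p = 0.00268) and CSPG4 (-0.75, adjusted p = 0.00922) fell. ACTA2 differed by 0.35 (adjusted p = 0.284). Of 14 endothelial genes 1 rose, the receptor KDR (0.75, adjusted p = 0.0166), also adjusted over the list alone, and PECAM1 differed by 0.48 (adjusted p = 0.2). Of 10 adipocyte genes 2 rose, LPL (1.44, adjusted p = 0.0036) and PPARG (0.74, adjusted p = 0.0306), also adjusted over the list alone, and FABP4 differed by -0.34 (adjusted p = 0.709). PPARG differed from fusion-negative tumours by 0.17 with PAX7-FOXO1 alone (adjusted p = 0.856). Its call was lost with equal weight of the 2 fusions (0.54, adjusted p = 0.187), as were those of KDR (0.67, adjusted p = 0.0653) and TAGLN (0.82, adjusted p = 0.115). Of 15 adult skeletal muscle genes 1 rose, the muscle enolase ENO3 (1.83, adjusted p = 6.2e-05), also adjusted over the list alone. The fusions differed here, with 1 higher and 2 lower for PAX3-FOXO1 alone (median -0.35) and 6 higher and 0 lower for PAX7-FOXO1 alone (median 1.54). The list had adjusted p = 0.989 and 0.416 with an estimated correlation. Of 9 B and plasma cell genes 1 rose, CD79B (1.03, adjusted p = 4.93e-05), also adjusted over the list alone, and it read 0.08 (adjusted p = 0.341) as the median of its probe sets and 0.07 (adjusted p = 0.359) without the _x_at and _s_at probe sets. Of 7 erythroid genes 1 passed, AHSP (0.14, adjusted p = 0.0437), or 0 adjusted over the list alone, and HBB differed by 0.27 (adjusted p = 0.752). Both AHSP means lay under the median of every array, and its call was lost after quantile normalization (adjusted p = 0.0657), with array medians subtracted (0.0758), with array weights (0.0618), with equal weight of the 2 fusions (0.103) and without the 5 arrays of highest 3' minus 5' value (0.0612). With limma 0 of 12 T cell and 0 of 12 macrophage genes passed, 0 of each at an unadjusted p under 0.05 and 0 adjusted over the list alone, and CD6 and LAPTM5 differed by -0.03 (adjusted p = 0.928) and 0.25 (adjusted p = 0.545).

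In all, 4479 of 19740 genes passed, 1852 higher and 2627 lower in fusion-positive tumours, and 875 of them differed at least 2-fold, 479 higher and 396 lower. Of the 29 lists, camera called 1 with an estimated correlation, against 6 with the preset correlation and 7 with fry. The count of 875 was 420 in the coded title series alone and 132 when limma's treat required a difference above 2-fold. With PAX7-FOXO1 alone SUZ12 (0.07, adjusted p = 0.832), TAP2 (0.38, adjusted p = 0.66), NOTCH1 (0.11, adjusted p = 0.86), TAGLN (0.44, adjusted p = 0.693) and GLI3 (-0.63, adjusted p = 0.221) did not pass. With PAX3-FOXO1 alone DNMT1 (-0.39, adjusted p = 0.118) and MYOZ2 (1.49, adjusted p = 0.0926) did not, and between the fusions none of these 7 genes passed (adjusted p = 0.325 to 0.681). Further named genes missed the threshold with 1 fusion alone. Among them with PAX7-FOXO1 were KDR (0.52, adjusted p = 0.458), HPRT1 (0.29, adjusted p = 0.509), CYRIA (0.36, adjusted p = 0.407) and FBLN1 (-0.89, adjusted p = 0.268). COL3A1 missed it with PAX7-FOXO1 (-0.40, adjusted p = 0.162) and with PAX3-FOXO1 (-0.30, adjusted p = 0.0596). In the numbered series alone 17 named calls were lost, with adjusted p from 0.056 to 0.403. These were AHSP, CCND1 (-0.97, adjusted p = 0.167), COL3A1, CYRIA, DNMT1, EPHA3, FBLN1, HPRT1, LPL (1.21, adjusted p = 0.0662), MYF6, MYOZ2, NOTCH1, PPARG, SESN1, SUZ12, TAP2 and TNFRSF10B. All but CCND1 were among the 37 lost in the smaller coded series, with adjusted p from 0.0514 to 0.953. The others lost there were CD79B, CSPG4, DLL1, EED, ENO3, EYA2, FAS, GLI3, HEY1, HOTAIR, JARID2, KDR, MYF5, MYOG, NNAT, NOTCH3, PAX7, PTCH1, SKP2, TAGLN and TTN.

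Each fusion was also compared with fusion-negative tumours on its own. PAX3-FOXO1 tumours had the largest increases in TFAP2B (log2 difference 6.88, adjusted p = 2.71e-21), CNR1 (5.82, adjusted p = 1e-14) and NOS1 (5.71, adjusted p = 2.84e-20), and the largest decreases in GAS2 (-4.11, adjusted p = 7.2e-10), CLMP (-3.63, adjusted p = 1.53e-11) and PAX7 (-3.53, adjusted p = 2.55e-06). PAX7-FOXO1 tumours had the largest increases in the same genes, TFAP2B (6.55, adjusted p = 1.34e-12), CNR1 (6.39, adjusted p = 2.35e-09) and NOS1 (6.08, adjusted p = 8.44e-13). Their largest decreases were in NPTX2 (-3.54, adjusted p = 0.00726, or 0.0735 with a rank-sum test), CLMP (-3.53, adjusted p = 5.79e-06) and DNM3OS, a non-coding RNA that hosts microRNAs (-3.46, adjusted p = 5.64e-07). For TFAP2B, CNR1, NOS1, CLMP and, with PAX3-FOXO1, GAS2 the lower mean lay under the median of every array. At least 2-fold, 471 genes were higher and 402 lower in PAX3-FOXO1 tumours, 873 in all, and 554 were higher and 339 lower in PAX7-FOXO1 tumours, 893 in all. The higher genes shared 287 members and the lower genes 172, with 1 gene in all called in opposite directions. Both contrasts used the same fusion-negative tumours. Independent lists of these sizes would share 13.2 and 6.9 genes, and unchanged groups sharing the same controls gave 0 shared genes in either direction in all 100 simulations, values that leave out the shared controls and the effects, respectively. With each contrast set against its own part of the fusion-negative tumours the median overlap was 201.5 higher and 88.5 lower genes over 100 divisions, where independent lists would share 9.47 and 3.92. Across genes the differences correlated at Pearson r = 0.724 and Spearman rho = 0.629, against a mean r of 0.338 (range -0.065 to 0.614) in 100 simulations of unchanged groups sharing the same controls. The simulations here and of the overlap gave all groups the same spread. In the data the median SD per gene was 0.42 in fusion-negative and 0.353 in PAX3-FOXO1 tumours. More variable shared controls raise the correlation of unchanged groups, so the simulated r may be too low. The covariance was 0.20 against a simulated 0.02, and with each contrast set against its own part of the fusion-negative tumours r was 0.608.

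The direct comparison of the fusions asked which genes differ by fusion partner. The largest differences were genes higher in the 7 PAX7-FOXO1 tumours, given as PAX3-FOXO1 minus PAX7-FOXO1. LINC01088, a long non-coding RNA, was higher in PAX7-FOXO1 tumours, at 9.79 ± 1.95 (SD, n = 7) against 4.45 ± 1.78 (SD, n = 26). Its log2 difference was -5.34 ± 0.64 (SE, adjusted p = 9.51e-08, 7 of 7 above the PAX3-FOXO1 median). NPY, neuropeptide Y, was 34.5-fold higher, at 11.92 ± 1.00 against 6.81 ± 1.68 (-5.11, adjusted p = 1.26e-04, 7 of 7). CDKN1C, a cyclin-dependent kinase inhibitor encoded at the imprinted 11p15 locus, was 7.72-fold higher, at 11.55 ± 0.50 against 8.60 ± 0.97 (-2.95, adjusted p = 8.73e-06, 7 of 7). FIGN was higher in PAX3-FOXO1 tumours (3.09, adjusted p = 0.00235), with 0 of 7 PAX7-FOXO1 tumours above the PAX3-FOXO1 median. The LINC01088 mean of PAX3-FOXO1 tumours and the FIGN mean of PAX7-FOXO1 tumours (4.81) lay under the median of every array, close to background. Of the 18 named genes past the threshold between the fusions this held for 7, the others being TENM1, OTP, PABPC4L, MYH2 and MYBPC1, so their sizes and order are not exact.

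TENM1, a teneurin of neuronal wiring, and OTP, a homeobox gene of the hypothalamus, were also higher with PAX7-FOXO1 (-4.63, adjusted p = 1.51e-04, and -4.37, adjusted p = 2.59e-05, 6 of 7 each). ZNF804A (2.48, adjusted p = 0.00592), NMU, neuromedin U (2.19, adjusted p = 0.0156), and GEM, a small GTPase (2.03, adjusted p = 0.0123), were higher with PAX3-FOXO1, as was PABPC4L (2.01, adjusted p = 0.00592). The lower means of TENM1 (3.95), OTP (5.26) and PABPC4L (5.12) were close to background. For ZNF804A, NMU, GEM and PABPC4L, 0 of 7 PAX7-FOXO1 tumours lay above the PAX3-FOXO1 median. FOXO1 was higher with PAX7-FOXO1 in 7 of 7 tumours (-1.06 ± 0.25 SE, adjusted p = 0.0134), a call lost without PAX7-FOXO1 replicate 4 (-0.96, adjusted p = 0.0636), 5 (-0.97, adjusted p = 0.0684) or 7 (-1.01, adjusted p = 0.0537). The NMU call was lost without replicate 1 (2.11, adjusted p = 0.0591) or 3 (1.96, adjusted p = 0.0585), and the GEM call without replicate 1 (1.86, adjusted p = 0.0666). With rank-sum tests the calls for OTP (adjusted p = 0.0851), TENM1 (0.156) and ZNF804A (0.0675) were lost.

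Several muscle genes were higher with PAX7-FOXO1. Of 29 sarcomere and muscle differentiation genes 6 were higher with PAX7-FOXO1 and 0 with PAX3-FOXO1 (9 and 0 adjusted over the list alone; median difference -1.59, adjusted p = 0.181 with an estimated correlation, 1.94e-16 with the preset correlation). Of 15 adult skeletal muscle genes 5 were higher with PAX7-FOXO1 and 0 with PAX3-FOXO1 (10 and 0 adjusted over the list alone; median -1.89, adjusted p = 0.134 with an estimated correlation, 5.5e-14 with the preset correlation), and the list passed without PAX7-FOXO1 replicate 4 (adjusted p = 0.0273). The lists share CKM, MYH2 and MYH7 and are not independent. MYH2, a fast myosin heavy chain, differed by -3.91 (adjusted p = 0.00175, 7 of 7) and MB, myoglobin, by -3.52 (adjusted p = 0.0357, 7 of 7). MYBPC1, a myosin-binding protein, differed by -4.35 (adjusted p = 0.0388) and TNNC1, slow troponin C, by -4.20 (adjusted p = 0.045), in 6 of 7 tumours each. The PAX3-FOXO1 means of MYH2 (4.59) and MYBPC1 (5.29) were close to background. MYH2 was uneven within both groups, from 3.88 to 12.36 in PAX7-FOXO1 and from 3.53 to 10.82 in PAX3-FOXO1 tumours. The lowest PAX7-FOXO1 values, 3.88 and 4.31, were themselves close to background. The count of 7 of 7 therefore does not mean that MYH2 was raised in every PAX7-FOXO1 tumour. The MYBPC1 and TNNC1 calls were lost without any 1 of PAX7-FOXO1 replicates 1, 2, 3, 5, 6 and 7, with differences of -3.91 to -4.58 and -3.71 to -4.23 and adjusted p up to 0.149 and 0.178. The MB call was lost without replicate 1, 2, 6 or 7, with differences of -3.02 to -3.27 and adjusted p up to 0.181. With the 3' minus 5' covariate TNNC1 (-3.76, adjusted p = 0.0957), MYBPC1 (-3.92, adjusted p = 0.0849) and MB (-3.35, adjusted p = 0.0666) lost their calls. With PAX7-FOXO1 replicates 1 and 7 counted as 1 tumour, TNNC1 (-3.99, adjusted p = 0.147), MYBPC1 (-4.14, adjusted p = 0.129) and MB (-3.18, adjusted p = 0.153) lost them too. With rank-sum tests none of the 4 genes passed (adjusted p = 0.0851 for MYH2 and TNNC1, 0.0744 for MYBPC1 and 0.128 for MB). ENO3, the most abundant adult muscle marker, differed by -0.47 (adjusted p = 0.816). The 3' minus 5' value was 1.66 ± 0.50 (SD, n = 7) with PAX7-FOXO1 and 2.07 ± 0.63 (SD, n = 26) with PAX3-FOXO1 (difference -0.41, exact permutation p = 0.125).

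**Figure D4:**
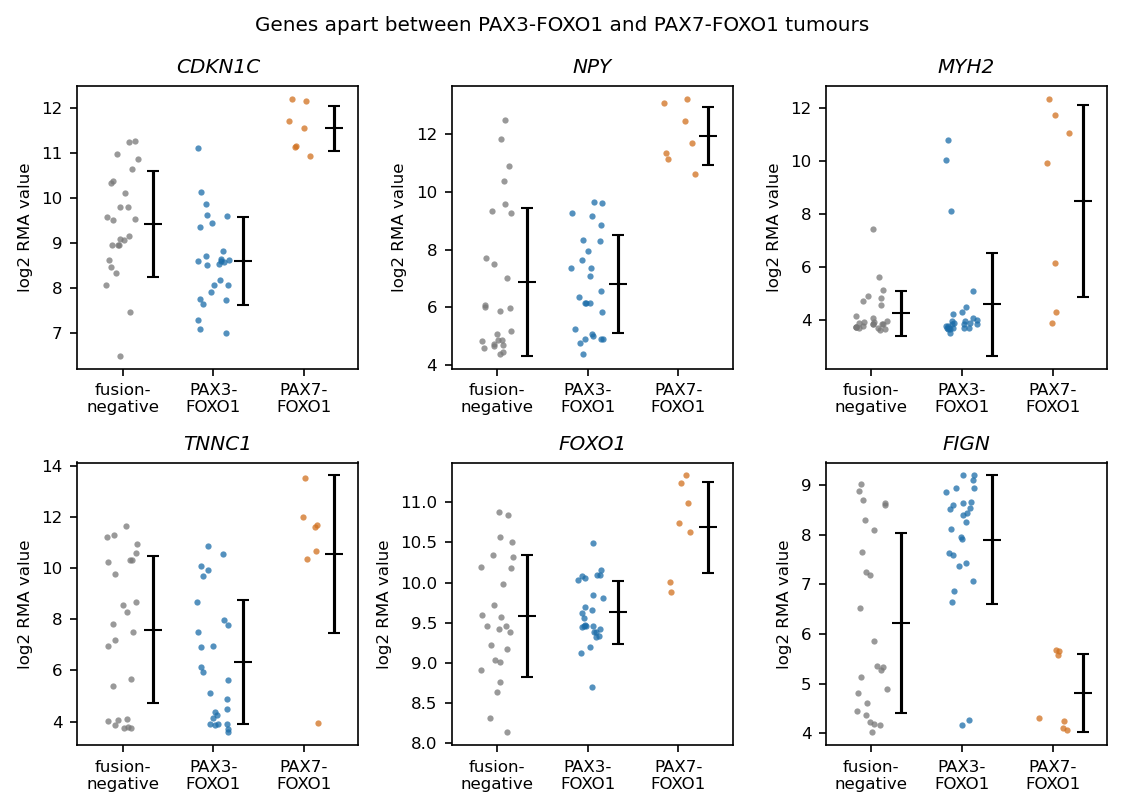
Each point is the log2 RMA value of 1 tumour for the gene named above its panel, and black marks give the group mean with its SD. CDKN1C, NPY, MYH2, TNNC1 and FOXO1 have higher means in PAX7-FOXO1 tumours and FIGN in PAX3-FOXO1 tumours, with CDKN1C means of 11.55 and 8.60. MYH2 values are uneven within both fusion groups.

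Further listed genes past the threshold were EPHA4, an ephrin receptor among the 17 RAS-MAPK output genes (-2.49, adjusted p = 0.00189, 7 of 7), and PDGFRB, a growth factor receptor among the 20 receptor tyrosine kinases (1.24, adjusted p = 0.0494, 6 of 7 PAX7-FOXO1 tumours below the PAX3-FOXO1 median). In the RAS-MAPK list 1 gene was lower and 0 higher in PAX3-FOXO1 tumours (1 and 1 adjusted over the list alone), and in the kinase list 0 lower and 1 higher (1 and 1). QDPR among the 26 reported targets differed by -0.99 (adjusted p = 0.0449, 7 of 7). Without any 1 of PAX7-FOXO1 replicates 1, 2, 3, 5 and 7 the PDGFRB and QDPR calls were lost, and the QDPR call also without replicate 4, as the median of its probe sets (-0.70, adjusted p = 0.144), without the 5 arrays of highest 3' minus 5' value (adjusted p = 0.0679) and with array medians subtracted (0.0565). The PDGFRB differences were then 1.07 to 1.31 with adjusted p up to 0.229, and those of QDPR -0.90 to -1.02 with adjusted p up to 0.167. Both calls were also lost in a fit of the 2 fusion groups alone (adjusted p = 0.0755 and 0.0965), among genes above the median mean (0.0547 and 0.0522), with replicates 1 and 7 as 1 tumour (adjusted p = 0.228 and 0.15), with rank-sum tests (0.104 and 0.0924) and with the 3' minus 5' covariate (0.0922 and 0.0947), and the PDGFRB call without the _x_at and _s_at probe sets (0.0541). With limma, 0 of 12 genes near CDK4 passed (6 at an unadjusted p under 0.05, median 0.49), 0 of 15 Notch pathway genes (10, median 0.62) and 0 of 26 cell cycle genes (7, median 0.56). Adjusted over the list alone, 2 Notch pathway genes were higher and 1 lower in PAX3-FOXO1 tumours, and 0 of the genes near CDK4 or of the cell cycle passed. The lists had adjusted p = 0.283, 0.181 and 0.688 with an estimated correlation, against 5.85e-05, 1.81e-04 and 5.71e-05 with the preset correlation. Endothelial genes and smooth muscle and pericyte genes had 0 of 14 and 0 of 12 past the threshold (4 and 2 unadjusted), with adjusted p = 0.688 and 0.414 with an estimated correlation against 0.00125 for both with the preset correlation. MHC class I and fibroblast lists had 0 of 13 and 0 of 16 (1 and 5 unadjusted), with adjusted p = 0.728 for both with an estimated correlation against 0.0297 with the preset correlation. PECAM1, LAPTM5, ACTA2, CD6 and COL3A1 differed by 0.71, 0.63, 0.63, 0.28 and 0.10 (adjusted p = 0.561, 0.627, 0.54, 0.695 and 0.895). FABP4, HBB and CD79B differed by 0.46, -0.76 and -0.43 (adjusted p = 0.895, 0.78 and 0.656).

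In all, 210 of 19740 genes passed between the fusions, 32 higher with PAX3-FOXO1 and 178 with PAX7-FOXO1, and 144 of them differed at least 2-fold, 22 and 122. Camera with an estimated correlation called 0 of 29 lists, with 5 at an unadjusted p under 0.05, against 10 called with the preset correlation and 5 with fry. The count of 144 was 59 among genes above the median mean, 395 with array weights and 86 with rank-sum tests.

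Fusion-negative tumours varied more between each other than PAX3-FOXO1 tumours. The distance of a tumour from the mean of the others in its group was taken as 1 minus the correlation. It was 0.0438 ± 0.0177 (SD, n = 25) in fusion-negative and 0.0305 ± 0.00926 (SD, n = 26) in PAX3-FOXO1 tumours (difference 0.0133, permutation p = 5.2e-04). The permutation exchanged distances computed once within the labelled groups. Distances within a group are not independent, so permutation p-values of this distance are approximate. In the numbered series alone the difference was 0.0143 (permutation p = 0.00121). The SD was larger in fusion-negative tumours for 12814 of 19740 genes (64.9%). The 3' minus 5' value also varied more in fusion-negative (SD 0.88, n = 25) than in PAX3-FOXO1 tumours (SD 0.63, n = 26). Neither measure of spread was adjusted for it, so a part of RNA quality in the wider spread was not tested. The fusion-positive minus fusion-negative differences of the 2 title series correlated across genes at Pearson r = 0.797 and Spearman rho = 0.61. Fitted separately, the numbered series had 761 genes at least 2-fold apart and the coded series 420, of which 255 were called in both with the same direction and 0 with opposite directions. A test of the difference between the series with limma gave 0 genes past the threshold, 903 at an unadjusted p under 0.05.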

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

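The test for adult muscle fibres, the tests of a fusion label, with their bounds, and the count of probe sets without a listed gene were chosen only after the results were seen. Among 42 tests for a tumour apart from the rest of the 7 PAX7-FOXO1 tumours, 7 genes had such a tumour. Chance would give 2.1 if the tests were independent, which they are not, since 6 of the 7 came from 1 tumour, so the number of genes is not set against chance. A lowest tumour stood apart in NOS1 (gap over range 0.751, 7.34 against the next 10.53), EPHA4 (0.621, 5.97 against 8.22), TNNC1 (0.671, 3.94 against 10.36), LINC01088 (0.627, 5.69 against 9.13), OTP (0.783, 4.09 against 9.77) and TENM1 (0.8, 3.11 against 8.77), and a highest tumour in NPTX2 (0.784, 11.50 against 5.32). In data outside the comparisons, 316 of 11721 probe sets without a gene in the annotation were at least 2-fold apart between fusion-positive and fusion-negative tumours, 213 higher and 103 lower.

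In 6 of these 7 genes, all but TNNC1, the tumour apart was the same 1 of the 7. On an axis from the fusion-negative mean at 0 to the PAX3-FOXO1 mean at 1, over genes at least 2-fold apart between these groups, it lay at 0.532. Fusion-negative tumours ran from -0.128 to 0.292, PAX3-FOXO1 tumours from 0.534 to 1.216 and the other 6 PAX7-FOXO1 tumours from 0.792 to 1.236. The bound first stated against a tumour without a fusion under a PAX7-FOXO1 label, a place inside the PAX3-FOXO1 range, was missed, and such a tumour is argued against only by a bound added after the position was seen, in that it lay 0.239 above the highest fusion-negative tumour, where the SD of the fusion-negative positions was 0.121. At the 2 genes that fully separated PAX3-FOXO1 from fusion-negative tumours its share beyond every fusion-negative tumour was 0.5, where fusion-negative tumours left out in turn reached 0.667, too few genes to decide, and no biological explanation was tested.

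Several muscle contractile genes were higher with PAX7-FOXO1 than with PAX3-FOXO1. A single tumour or a near-duplicate pair of arrays is argued against, since the median difference of 29 sarcomere genes stayed at 1.357 or more, of 1.585, in every set without 1 array or with the pair as 1. RNA quality as the whole cause is argued against as well, since the median was 1.38 with the 3' minus 5' covariate, for which 2196 genes passed. However, 3 of the 4 named genes lost their calls, TNNC1 by moving from -4.20 to -3.76, MYBPC1 from -4.35 to -3.92 and MB from -3.52 to -3.35. Their SEs of 1.13, 1.15 and 0.92 describe the spread between tumours and do not test these shifts. Adult muscle fibres in the specimens and a difference between the tumours themselves cannot be told apart, because the ratio of the developmental to the adult list was 0.238 (95% interval 0.064 to 0.572), wide enough to hold both. The median difference was 0.449 over 12 developmental genes, from MYH8 at 2.417 to MYOG at -0.26, and 1.885 over 15 adult genes, from MYH2 at 3.91 to MYLK2 at -0.013.

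FOXO1 was higher with PAX7-FOXO1 by 1.063. A gain of the whole region is argued against, since the median of the 10 nearest genes on each side whose mean lay above that of the median gene was -0.038 (95% interval -0.273 to 0.128). A single tumour or the near-duplicate pair is argued against too, since the difference stayed at 0.956 or more, although the call itself was lost without replicate 4, 5 or 7. A gain of the fused gene alone, or more transcription from it, may remain and was not tested.

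Chance is argued against for 5 counts of genes by 100 splits of the tumours into groups of the same sizes, the real one included. Since the real split counts, 1 of 100 is the lowest value possible, so chance is bounded and not excluded. The splits treated every array as a separate tumour. The number of splits with as many genes was 1 for each gene count, with 4479 real against 113 at most otherwise for fusion status, and 875 against 24 at least 2-fold. The same held for PAX3-FOXO1 against fusion-negative tumours (873 against 133), PAX7-FOXO1 against fusion-negative tumours (893 against 213) and between the fusions (144 against 18). For lists by fusion status 4 of 100 splits, the real one included, called as many (1 real, 1 at most otherwise), and the list called is the one that may come from these tumours. Between the fusions 0 lists were called, so all 100 splits gave as many by construction, which says nothing about chance.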

How the results depend on the processing

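The alternatives chosen after seeing the data were the PAX7-FOXO1 pair counted as 1 tumour, the 3 least correlated arrays left out and the 5 arrays with the highest 3' minus 5' value left out. Of the comparisons of a main result with an alternative, 103 gave the same result and 18 moved, and of those of a named gene 1658 were the same, 152 lost the call and 2 reversed. Reversed were MMP2 with the median of probe sets (0.0227, adjusted p = 0.797) and HES1 without the _x_at and _s_at probe sets (0.0621, adjusted p = 0.395), each of which follows from the probe sets read. Lost named calls numbered 12 with the median of probe sets, 11 with rank-sum tests, 10 with equal weight of the 2 fusions and 8 without the _x_at and _s_at probe sets. The coded series alone, with fewer tumours, gave 722 genes and 420 at least 2-fold for fusion status and lost 37 named calls, the numbered series lost 17, and treat gave 132 by its stricter rule. Between the fusions 59 genes were at least 2-fold apart among genes above the median mean, where fewer were tested, 395 with array weights and 86 with rank-sum tests, where the cause was not tested. Leaving out 1 PAX7-FOXO1 tumour gave 106 to 197 genes between the fusions and 688 to 1012 against fusion-negative tumours, and the pair as 1 tumour 106 and 701. Lists called by fusion status were 6 with the preset correlation, 7 with fry, 3 among genes above the median mean, and 2 each with title series as a covariate, quantile normalization and the median of probe sets. Between the fusions they were 10 with the preset correlation, 5 with fry and 0 to 1 without 1 PAX7-FOXO1 tumour. The correlation of the fusions was 0.608 with separate controls and 0.774 above the median mean, and that of the title series 0.61 by rank. The 3 least correlated arrays left out gave 916 genes at least 2-fold apart by fusion status and 172 between the fusions, and the 5 of lowest quality 907 and 147. Signal near background limits the dim genes.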

Other observations

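The tests by HOX cluster and by autosome were chosen only after the results were seen. Some HOX genes were lower in fusion-positive tumours in every cluster, with 1 of 1 measured HOXA gene lower, 6 of 10 HOXB, 7 of 9 HOXC and 4 of 8 HOXD genes, and 0 higher in each. Only 28 of the 39 listed HOX genes were among the genes tested. With 1 gene, HOXA was almost wholly absent, so its value does not describe that cluster. Median log2 differences were -0.44 for HOXA, -0.38 for HOXB, -0.81 for HOXC and -0.26 for HOXD.

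By autosome, camera with an estimated correlation called 0 of 44 tests over both comparisons, with 3 at an unadjusted p under 0.05. Chromosome 8 had a median difference between fusion-positive and fusion-negative tumours of -0.21 over 716 genes (p = 0.0308, adjusted p = 0.452), chromosome 9 of 0.03 (p = 0.0275, adjusted p = 0.452) and chromosome 11 of -0.10 (p = 0.0276, adjusted p = 0.452).

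The most similar arrays, PAX7-FOXO1 replicates 1 and 7, correlated at 0.985, where the next pair reached 0.973 and the median pair 0.923. Each tumour's most similar tumour was of the same title series for 29 of 58.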
